A study of Mus musculus with 12 samples.

How the data were processed

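Small RNAs were measured in 10 libraries, KO and WT pairs of testis, caput, corpus and cauda at 13 months and of caput at 2 months, and the caput transcriptome at 13 months in 2 libraries. Per the labels' protocols, tissue came from 7 WT and 7 KO C57BL/6 mice at 13 months and was pooled in place of replicates. Per the labels' protocols, testis and corpus were taken directly, and caput and cauda were first punctured and left in buffer so that spermatozoa could leave. Small RNA libraries were selected at 18 to 40 nt with the TruSeq small RNA kit and run on 1 of 2 instrument types, per the labels' protocols, which do not say which library ran on which instrument. TopHat2, Bowtie 0.12.7 and the mm9 build are named per the submitters' processing notes, without saying which step used them.

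The small RNA files hold a count of reads for each distinct sequence, and per the file headers the authors matched each sequence to miRBase, Rfam or GenBank entries with up to 2 mismatches, and piRNA entries appear among the matches. Class and strand were taken from the matched entry, and sequences listed on the minus strand were turned back to the strand of the read. In both 2-month files a spreadsheet had turned rank and count into a date for 5531 sequences in WT and 5419 in KO, whose count was read back from the month. Ranks missing from a file show how many collapsed reads have no line in it, and these reads were not used here. The RPKM values per RefSeq transcript were deposited by the authors, who ran GFOLD per the file headers. The log2 fold changes and GFOLD values are those of the authors' deposited table, where the E-FDR column deposited by the authors as a p-value is 1 in all 28344 transcripts. By the authors' deposited table, GFOLD values put 304 transcripts at 1 or more and 4266 at -1 or less.

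Each class was given as a share of the classified reads of its library, with a Clopper-Pearson interval at 95%, and KO over WT ratios of shares had exact conditional binomial intervals. Sequencing reads carry no molecular identifiers, so these intervals and the floor of 3 counts used for a value of 0 cover counting error only. The 1 library per group gave no test between genotypes and no p-value. At the depths listed with the results, the floor lay between 1.03e-05% and 7.78e-05% of classified reads.

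Counts of miRNAs were summed by mature name on the plus strand, and names sharing their most abundant sequence in a library with at least 20 reads were merged. The merging was refined after a first result had been seen. A miRNA was tested with at least 100 RPM (miRNA reads as the base) in a library of the pair, and called higher or lower at a 2-fold ratio whose interval excluded 1. Reads were also counted by first base, from a 15 nt inner sequence, at the usual first base and 1 to 3 nt away. Names sharing an inner sequence, such as miR-27a-3p and miR-27b-3p, share that count.

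Transcripts were reduced from 28344 to 22021 genes by keeping the transcript with the highest mean RPKM. Of the transcripts 27575 had an accession in the RefSeq table used for names, and 42 names that a spreadsheet had turned into dates were restored through it. Differences were taken as log2(RPKM + 1), for genes with at least 1 RPKM in a library, and a gene was called at a difference of at least 1. Reads behind a gene were recovered from the RPKM values and the log2 fold change of the authors' deposited table. Of 3040 transcripts with up to 20 recovered reads in both libraries, 89.2% came out whole within 0.1 reads, and no count test was run on them. Medians of 31 fixed gene lists were placed among 10000 random lists matched on mean expression, each member drawn from its 200 neighbours, for lists with at least 3 tested genes. These percentiles describe these libraries and are not a test.

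The lists, the comparisons, the 2-fold and expression thresholds and the rule for named genes were chosen before the data were examined, while counting by first base and comparing piRNA sequences with testis were chosen after. The rule names Gpx5, the 10 genes with the largest difference in each direction at 5 RPKM or more, up to 4 members per list by difference or by mean, the 5 miRNAs with the largest difference in each direction and pair at 1000 RPM or more, the 5 most abundant in caput at 13 months, and at most 3 single sequences per other class and pair. Alternatives covered the denominator, distinct sequences, low counts, abundant sequences, lengths, miRNA scaling with edgeR TMM and median of ratios, depth, pseudocounts of 0.1 and 5, filters and centring. Further alternatives were added after seeing the data: reads without a mismatch, dates left out, lengths of 18 to 38 nt, miRNA counts by first base or inner sequence, genes without testis fragments, centring on the caput secretory list, each testis library alone, and spermatogenic miRNAs without miR-871-3p. Genes with testis fragments are those with at least 10 RPM of small RNA reads from their mRNA in both testis libraries. Most reads of the mRNA class in both testis libraries were 24 to 32 nt long, the length of piRNA reads.

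Calls were tested on simulated data. Both libraries of a simulated pair were drawn from a shared profile with counting error only. The rates below therefore leave out variation between animals, dissections and libraries, and sequences missing from a file. With 3-, 6- or 12-fold differences, all 55, 37, 44, 61 and 30 changed miRNAs of caput, corpus, cauda, testis and 2-month caput were recovered, and 0 unchanged ones were called. In the simulated transcriptome 62 of 64 genes changed 4-fold, 62 of 63 changed 8-fold and 64 of 66 changed 16-fold were recovered, and 41 of 14258 unchanged genes were called. Of 200 random lists, 10 fell outside the middle 95%. Recovered WT reads lay within 5% of the simulated ones for 100% of 282 genes. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16 were used.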

Results

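The data compare wild-type (WT) mice with mice labelled as knockout (KO) for Gpx5, the gene of an epididymal secreted glutathione peroxidase. Small RNAs were sequenced from testis, caput, corpus and cauda epididymidis at 13 months and from caput at 2 months, which makes 5 KO and WT pairs from 10 libraries. A further 2 libraries hold the caput transcriptome at 13 months. Each group is 1 library from pooled animals, so no value has a replicate error, no difference between genotypes has a replicate check, and intervals cover counting error only.

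The small RNA files listed 13825045 classified reads for WT and 18362642 for KO caput at 13 months. Corpus had 29049669 in WT and 8356569 in KO, and cauda had 16432212 and 11451522. Testis had 8567091 in WT and 9834580 in KO, and caput at 2 months had 3855476 and 7673814. In each 13-month small RNA file 9 to 23 of the 100 most abundant ranks have no line (11 in both corpus files), so a very low value of a single sequence can mean that it is not listed. The transcriptome rested on 14348655 reads in WT and 13929327 in KO.

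The targeted gene was compared first, because it checks the labels. Gpx5 (NM_010343) had 8474 RPKM in the WT and 918 RPKM in the KO caput transcriptome, or 233031 and 24504 recovered reads. The KO level was 9.23-fold lower (9.11 to 9.36), a log2 difference of -3.21, so the transcript was lower in the KO library and still abundant, and which part of the gene the remaining reads cover was not analysed here. In the authors' deposited table the log2 fold change of Gpx5 was -3.14 and its GFOLD value -3.11. Small RNA fragments of Gpx5 were listed at 58.4 RPM (classified reads of the library as the base) in WT caput at 13 months (54.5 to 62.6) and at 1.36 in KO caput (0.881 to 2.01). Both 2-month caput libraries listed 0 such fragments, where the floor of 3 counts is 0.778 RPM in WT and 0.391 RPM in KO, and both corpus and both testis libraries also listed 0, while cauda had 3 reads in WT and 0 in KO. Among the small RNA libraries these fragments therefore check the genotype of the 13-month caput pair alone.

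The classes of small RNA were compared between genotypes within each tissue and age. In caput at 13 months, piRNA reads made up 15.8% of the classified reads in WT and 0.655% in KO, which is 24.1-fold lower in the KO library (23.95 to 24.23; log2 -4.59). The other tissues showed no such gap. The piRNA share was 0.900% in WT and 1.37% in KO corpus (log2 0.61), 0.591% and 0.914% in cauda (log2 0.63), 64.1% and 62.8% in testis (log2 -0.03), and 0.0703% and 0.0504% in caput at 2 months (log2 -0.48). Counted as distinct sequences at equal depth, the log2 difference in caput at 13 months was -1.92.

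**Figure D1:**
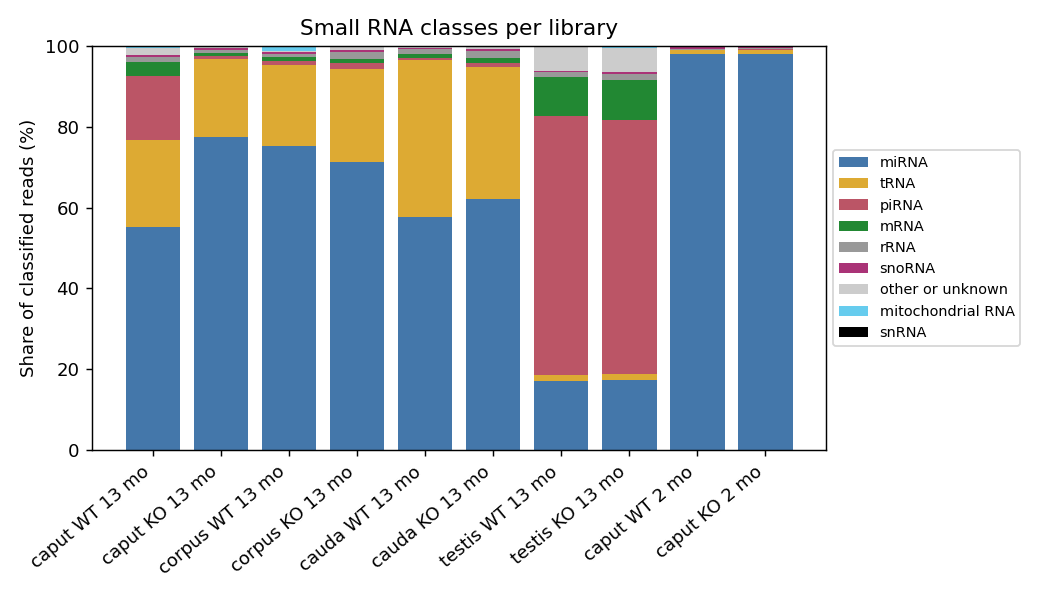
Share of classified reads (percent, vertical axis) of each small RNA class in the 10 libraries (horizontal axis, genotype and age in months). The piRNA part takes 15.8% in WT caput at 13 months and 0.655% in KO caput, and 64.1% and 62.8% in testis.

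The piRNA reads of the WT caput had the length and first base of the testis piRNAs. In WT caput 95.2% of piRNA reads were 24 to 32 nt long and 87.6% began with T, against 96.1% and 88.6% in WT testis and 71.4% and 44.4% in KO caput. These shares were 70.4% and 39.1% in WT corpus, 73.1% and 55.1% in KO corpus, 53.1% and 31.1% in WT cauda and 57.7% and 29.1% in KO cauda. Many reads of the piRNA class in corpus and cauda thus lacked the length or first base of testis piRNAs. Of 4153 piRNA sequences with at least 20 RPM in testis, 99.4% were listed in WT caput, at a median of 0.203 of their testis level (interquartile range 0.169 to 0.251). In KO caput the median was 0.00182. Pearson's r with testis across these sequences was 0.89 for WT caput (Spearman's rho 0.81) and 0.05 for KO caput (rho 0.66), where sequences are not independent replicates. The most abundant sequence of entry piR-125360 was at 932 RPM in WT and 11.8 RPM in KO caput, while 2 sequences of entry piR-22206 were near equal, at 859 and 794 and at 588 and 541 RPM.

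**Figure D2:**
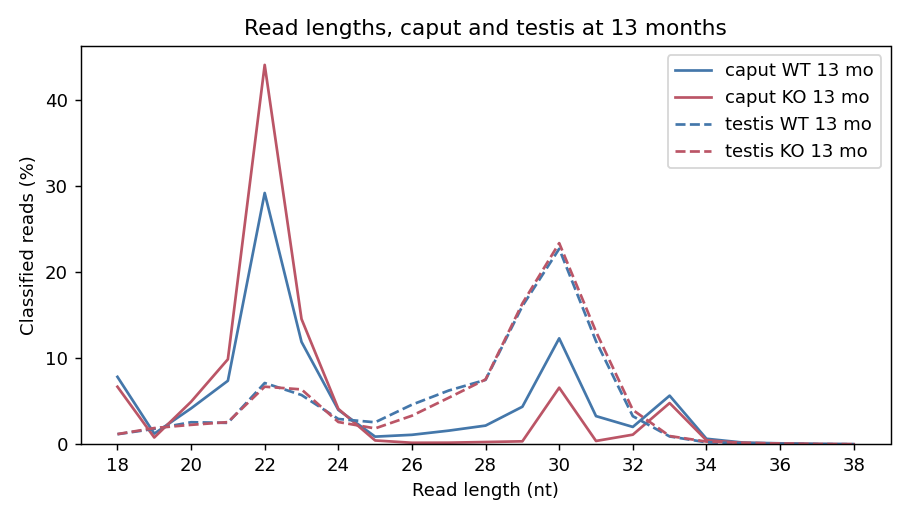
Percent of classified reads (vertical axis) by read length in nt (horizontal axis) for caput (solid) and testis (dashed) at 13 months, WT in blue and KO in red. WT caput exceeds KO caput between 25 and 32 nt, the range where both testis libraries have most of their reads.

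Reads assigned to mRNA and to mitochondrial RNA were also lower in the KO caput at 13 months. The mRNA class had 3.45% of reads in WT and 0.844% in KO (log2 -2.03), and mitochondrial RNA had 0.257% and 0.0818% (log2 -1.65). Of the mRNA reads in WT caput, 67.9% were 24 to 32 nt long and 54.2% began with T. In KO caput these shares were 28% and 20.1%, and in WT testis 83.15% and 66.6%. Many mRNA reads of WT caput thus had the length and first base of piRNA reads, so this difference may not be separate from that of piRNAs. The miRNA share was 55.2% in WT and 77.4% in KO caput (log2 0.49), and tRNA fragments had 21.5% and 19.5% (log2 -0.15). In corpus, mitochondrial RNA was lower in KO (1.08% to 0.298%, log2 -1.86). Of these reads 82.85% were 20 nt long in WT, while in KO the most frequent length, 21 nt, held 13.9%. The corpus mitochondrial difference thus rests on reads of 1 length. Corpus rRNA was higher in KO (0.651% to 1.63%, log2 1.33), but its difference was 0.66 without the 10 most abundant sequences and 0.12 as distinct sequences. A single 20 nt sequence was at 6503 RPM as rRNA in KO corpus and not listed as rRNA in WT corpus. Whether it was listed there under another class was not checked. Such changes of class occur: at 2 months a 21 nt sequence of caput was rRNA at 180.5 RPM in WT and snRNA at 164 RPM in KO. Cauda and testis had snRNA log2 differences of 1.21 and 1.15, at shares of at most 0.272%, which were 0.64 and 0.58 without the 10 most abundant sequences and 0.07 and 0.45 as distinct sequences.

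Fragments of tRNA were compared by tissue, age and amino acid, since they are abundant in the epididymis. They took 38.8% of reads in WT and 32.7% in KO cauda, 20.1% and 22.9% in corpus, 1.48% and 1.46% in testis, and 1% in both caput libraries at 2 months. As distinct sequences at equal depth the KO over WT log2 value of tRNA was 1.43 in caput at 13 months, -0.20 in corpus and 0.02 in testis, and in cauda it was 0.02 without the 10 most abundant sequences, so these directions depend on the counting. The cauda share was 1.80-fold that of caput in WT and 1.68-fold in KO. By amino acid, only plus-strand reads starting at or near the first base of the tRNA were counted. Fragments from the rest of each tRNA are therefore not in the values that follow. Such fragments of tRNA-Gly made up 55.7% of tRNA reads in WT and 57.1% in KO caput at 13 months, followed by tRNA-Val with 28.8% and 28%. Fragments of tRNA-Glu had 8.26e-05% of classified reads in WT corpus (24 reads) and 1.57% in KO corpus (131204 reads), where the limit on unlisted sequences applies. Fragments of tRNA-Lys had 0.148% of classified reads in WT corpus and 0.59% in KO, and tRNA-His had 0.0745% in WT cauda and 0.028% in KO. Fragments from the start of tRNA-Asp were at or under 0.00117% in every library.

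The caput at 2 and 13 months was compared within each genotype. The tRNA share was 21.4-fold higher at 13 months in WT and 19.5-fold in KO, and the miRNA share was lower, with log2 values of -0.83 and -0.34. The 2-month files also hold reads of up to 47 nt against 38 nt at 13 months in caput and list fewer distinct sequences (17537 in WT, 23330 in KO), so age cannot be told apart from how these files were made. The piRNA share of testis was 4.06-fold that of caput in WT and 95.9-fold in KO.

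Individual miRNAs were compared in each pair. In caput at 13 months, 48 of 131 tested miRNAs were at least 2-fold lower in the KO library and 0 were higher. The fixed set of spermatogenic miRNAs made up the clearest group: all 14 tested members were lower, and their sum was 20800 RPM in WT and 801 RPM in KO (log2 -4.70), with miRNA reads as the base here and below. Within it, miR-871-3p was at 8530 and 60.6 RPM (log2 -7.14) and miR-34c-5p at 6602 and 518 (log2 -3.67). This sum was near equal in corpus (log2 0.07) and caput at 2 months (0.01), and 0.39 in cauda and 0.74 in testis. Without miR-871-3p, which carries most of the testis value and whose testis ratio depends on the first base, the sum was at 0.30 in testis and -4.05 in caput at 13 months.

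The scaling matters for the caput at 13 months. Trimmed-mean (TMM) scaling placed the centre of the miRNAs at -0.86 and median-of-ratios scaling at -0.94. Relative to those centres the counts were 6 higher and 24 lower with TMM and 11 higher and 26 lower with median of ratios. The sum of the spermatogenic miRNAs was then at log2 -3.84 and -3.76, miR-871-3p at -6.28 and -6.20, and miR-34c-5p at -2.82 and -2.73. The 5 most abundant caput miRNAs were miR-10b-5p (log2 0.25), miR-10a-5p (0.12), miR-143-3p (-0.03), miR-191-5p (-0.44) and miR-148a-3p (-0.06). With TMM they were at 1.11, 0.98, 0.82, 0.42 and 0.80. Beyond those named, miR-25-3p (-1.36) and miR-146a-5p (-1.27) were lower in KO and came to -0.50 and -0.41 with TMM, while miR-125a-5p (0.41), miR-141-3p (0.41), miR-126a-5p (0.29) and let-7f-5p (0.20) were the highest among miRNAs with at least 1000 RPM in a library and passed 2-fold with TMM (1.27, 1.27, 1.14 and 1.06).

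The other fixed miRNA sets moved with the scaling in caput at 13 months. The let-7 family was at log2 -0.65 and at 0.21 with TMM, the leukocyte set at -0.69 and 0.17, the erythroid set at -0.77 and 0.09, the muscle set at -0.05 and 0.81, and the stress and p53 set at -0.90 and -0.05 (0.04 with median of ratios). The miR-17-92 family was at -1.20 and -0.34, the miR-200 family at 0.10 and 0.95, and the epididymal epithelium set at 0.19 and 1.05. In cauda the miR-200 family was at log2 3.31, carried by miR-141-3p, and the leukocyte set at -1.78, carried by miR-21a-5p, but at other starts these miRNAs were at 0.03 and 0.28. In corpus the leukocyte set was at 1.43, carried by miR-21a-5p, whose reads at other starts went the other way. The corpus erythroid set was at 3.65, carried by miR-3107-5p/miR-486-5p. Reads of that miRNA were at 9.55 at the usual first base but at 1.45 at other starts (9.28 and 25.4 RPM).

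Corpus, cauda and testis also showed large single-miRNA ratios, and most of those held only for reads with the usual first base. Corpus had 35 higher and 7 lower of 132 miRNAs, cauda 20 and 4 of 108, testis 8 and 16 of 170, and caput at 2 months 7 and 0 of 38. In corpus miR-21a-5p was at 16.3 RPM in WT and 10710 RPM in KO, and reads starting 1 to 3 nt away were at 3255 and 295. Likewise miR-127-3p, miR-182-5p and miR-27b-3p were at log2 10.32, 8.69 and 8.02 by name and at -0.94, -4.42 and 0.23 at other starts. By contrast miR-3107-5p/miR-486-5p (9.12) and miR-183-5p (5.57; named after its values were seen) in corpus were at 1.45 and 3.85 at other starts. In testis miR-871-3p was at 5.73 by name and -1.96 at other starts. Without the miRNAs whose starts disagree by 4-fold, miR-3107-5p/miR-486-5p among them, corpus had 6 higher and 5 lower. The caput differences of miR-871-3p and miR-34c-5p were at log2 -6.35 and -3.21 at other starts, while miR-27b-3p in caput was at -4.98 by name and 0.03 at other starts.

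**Figure D3:**
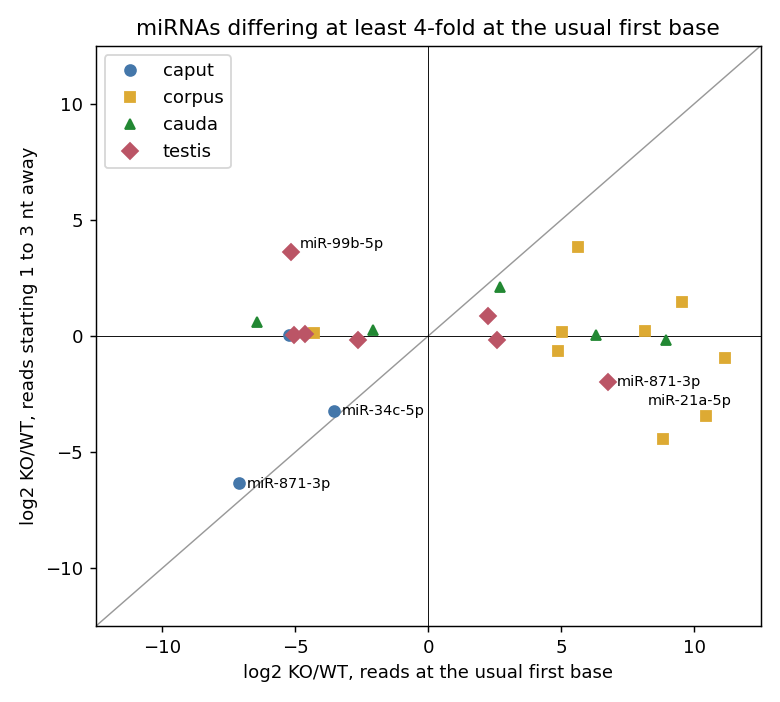
Log2 KO over WT of 24 cases (18 miRNAs with at least 1000 RPM, by tissue) at 13 months that differ at least 4-fold at the usual first base (horizontal axis), against the same miRNA's reads starting 1 to 3 nt away (vertical axis). The grey line marks equal values. In 19 of the 24 the other starts do not follow, and miR-871-3p and miR-34c-5p of caput lie near the line.

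In cauda miR-16-5p (log2 -6.15) and miR-21a-5p (-2.82) were lower in KO by name and at 0.62 and 0.28 at other starts, and miR-27b-3p (7.65), miR-141-3p (6.05), miR-199a-5p (2.84), miR-125b-5p (1.81) and miR-151-5p (1.70) higher. Of these miR-199a-5p and miR-125b-5p were also higher at other starts (2.12 and 1.89), while miR-27b-3p, miR-141-3p and miR-151-5p were at -0.16, 0.03 and 0.49. In testis miR-34a-5p (-5.66), miR-15b-5p (-4.50), miR-99b-5p (-4.20) and miR-148a-3p (-3.61) were lower by name and at 0.06, 0.11, 3.61 and -0.16 at other starts. In corpus miR-148a-3p (-3.81) and miR-142-5p (-1.72) were lower by name and at 0.12 and -1.11 at other starts. In caput at 2 months miR-30a-5p (1.18), miR-99b-5p (1.07) and miR-141-3p (1.02) were the highest among miRNAs with at least 1000 RPM in a library, and with TMM or median of ratios 1 miRNA was higher and 0 lower. The TMM centres of the other pairs were at -0.05 in corpus, 0.30 in cauda, 0.08 in testis and 0.64 in caput at 2 months, and the median-of-ratios centres at 0.17, 0.42, -0.01 and 0.60. In cauda the split was 15 higher and 4 lower with TMM and 12 and 6 with median of ratios.

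The caput transcriptome at 13 months was compared on log2(RPKM + 1), a scale that understates the difference of genes with low values. Among 15000 genes with at least 1 RPKM in a library, 3321 were at least 2-fold lower in the KO library and 415 higher. The largest difference was that of Mir147 (log2 -7.15; 160 recovered reads in WT and 0 in KO), and spermatogenic transcripts were among those next to it. Mael had 306 RPKM in WT and 1.67 in KO, Fabp9 743 and 6.14, Ldhc 603 and 5.15, and Tnp1 2329 and 24.1, with log2 differences of -6.84, -6.70, -6.62 and -6.54. Genes at least 8-fold lower numbered 1141 and held 12.9% of the WT reads and 0.465% of the KO reads. These totals include the targeted gene Gpx5, with 233031 recovered reads in WT and 24504 in KO.

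Fixed lists of germ cell and interstitial genes were all lower in KO. All 21 tested spermatid and sperm transcripts were lower, with a median of -5.21 at percentile 0 of 10000 random lists, including Prm2 (2745 and 51.7 RPKM), Prm1 (2090 and 24.4) and Tnp2 (1742 and 19.6). Of 20 piRNA pathway genes 18 were lower (median -3.01, percentile 0), including Gtsf1 (-6.45), Ddx4 (-5.86) and Tdrd6 (-5.75). All 6 Leydig cell markers were lower (median -3.95, percentile 0.02), including Insl3 (219 and 1.47 RPKM), Cyp17a1 (70 and 7.18), Hsd3b6 (-4.63), Hsd3b1 (-4.14) and Cyp11a1 (-3.77).

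The medians of the initial segment and caput secretory list and of the beta-defensins were higher in KO. Of 30 initial segment and caput secretory genes 20 were higher and 0 lower (median 1.13, percentile 100, where the middle 95% of random lists of like expression lay between 0.54 and 0.93), including Lcn5 (770 and 2294 RPKM), Adam7 (2383 and 6373), Spag11b (3007 and 7241) and Cst11 (1464 and 3292). Of 31 beta-defensins 15 were higher (median 0.99, percentile 100, random lists 0.21 to 0.80), including Defb20 (2506 and 6589 RPKM), Defb18 (634 and 1961) and Defb2 (27.1 and 103). In the same libraries basal cell markers were at 0.87, erythroid markers at 1.01 and spermatid transcripts at -5.21. With values centred on the caput secretory list, 8 genes were higher and 8112 lower, so the split of higher and lower genes depends on the scaling. Spinkl was 14.5-fold higher (11.9 to 17.9; 106 and 1494 recovered reads, log2 3.76), 2210415F13Rik 3.49-fold (3.39 to 3.60) and Ly6d 3.48-fold (2.45 to 5.04).

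**Figure D4:**
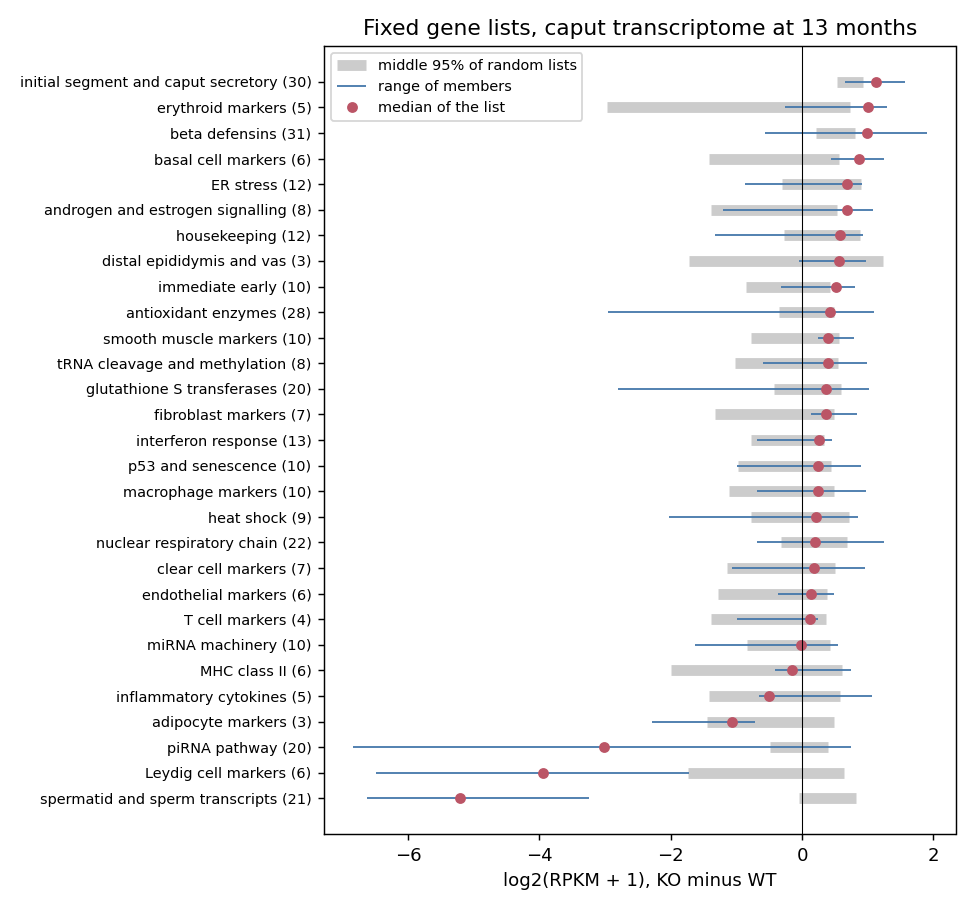
Median log2(RPKM + 1) difference, KO minus WT (horizontal axis), of each fixed gene list with at least 3 tested genes (vertical axis, number of genes in brackets). Red points are medians, blue lines the range of the members and grey bars the middle 95% of random lists matched on expression. Spermatid, Leydig and piRNA pathway lists lie at -5.21, -3.95 and -3.01, and the caput secretory list at 1.13.

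Of 28 tested antioxidant genes 1 was higher and 3 lower, with a median of 0.42 (percentile 92.8). Gpx8 was higher (1.09), Txnrd3 (31.3 and 3.19 RPKM, -2.95), Gpx4 (265 and 94.8, -1.47) and Prdx4 (-1.34) were lower, and Prdx1 was at 0.94, under the 2-fold limit. Spermatid transcripts (-5.21) and Leydig cell markers (-3.95) were lower in the same libraries. Glutathione S-transferases had a median of 0.37 (percentile 71.7; 1 higher and 3 lower of 20), with Mgst1 at 1.02, Gstm7 at 0.72, Gstm5 at -2.80 (246 and 34.4 RPKM) and Gsta2 at -2.72. Heat shock genes had a median of 0.21 (percentile 42.5; 0 higher and 3 lower of 9), with Hsp90aa1 at -2.03 and Dnajb1 at -1.54. ER stress genes had a median of 0.69 (percentile 67.3, random lists -0.31 to 0.90). Androgen and estrogen signalling was near it at 0.68 (99.7), against lower random lists (-1.38 to 0.54). Nuclear respiratory chain genes were at 0.19 (27), p53 and senescence genes at 0.25 (82.7) and miRNA machinery at -0.02 (42.5). Genes of tRNA cleavage and methylation were at 0.39 (86.5).

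Markers of other cells and of inflammation were measured in the same libraries. Basal cell markers had a median of 0.87 (percentile 100, random lists -1.41 to 0.56). Erythroid markers were at 1.01 (99.96, random lists -2.97 to 0.73) with Hbb-b1 at 1.30. Immediate early genes were at 0.52 (99.5, random lists -0.86 to 0.43), under the housekeeping median of 0.58 (50.2, random lists -0.28 to 0.89). The random lists differ with expression, so a high percentile does not mean a larger difference than in another list. Smooth muscle markers were at 0.40 (86.5), fibroblast markers 0.36 (90.6), endothelial markers 0.13 (80.4), macrophage markers 0.24 (77.3), T cell markers 0.12 (87.1) and clear cell markers 0.18 (75.9). Interferon response genes were at 0.26 (92), MHC class II genes at -0.15 (35.9), inflammatory cytokines at -0.50 (14.3) with Lcn2 at 1.07, adipocyte markers at -1.06 (17.1), distal epididymis genes at 0.57 (37.2) and housekeeping genes at 0.58 (50.2). The lists of B and plasma cell markers and of neutrophil markers had 1 and 0 tested genes and no median.

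Some genes picked by the naming rule rest on few reads or overlap small RNA loci. Mir147 was at least 51.8-fold lower against the floor of 3 counts (41.6-fold at the lower end of the counting interval), and Cox8c had 825 and 2 (400-fold lower, 111 to 3312). Snord49a had 0 and 8 reads, at least 2.75-fold higher against that floor (1.76-fold at the lower end), and Mir29a had 3 and 18 (6.18-fold, 1.80 to 32.8). Mir30b had 3 and 13 reads (4.46-fold, 1.23 to 24.4), Mir875 1 and 6 (6.18-fold, 0.75 to 284) and Mir204 1 and 5 (5.15-fold, 0.576 to 244), the last 2 with intervals that include 1. Tuba3a (-6.59) and Tuba3b (-6.58) are near-identical copies whose reads can be shared, and Cypt12 (-6.60) and 1700061J05Rik (-6.52) complete the named lower genes.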

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

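The tests of germ-cell RNA, of caput-made piRNAs in both forms, of abundant sequences, of lost first bases, of naming and of less muscle with no dilution were chosen only after the result was seen. The tests of interstitial cells, of dilution and of muscle, connective tissue and vessel against the genes without testis fragments were set before it.

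The first pattern is the lower level of piRNA reads and spermatogenic transcripts in KO caput at 13 months, which set caput apart from the other tissues by log2 -5.20 (corpus) and -5.22 (cauda). A few abundant sequences are argued against, since without the 10 most abundant piRNA sequences the log2 difference was -4.87. Testis tissue in the WT caput pool is a candidate explanation, since the median of the Leydig cell markers was -3.95, which spermatozoa in the duct alone would not bring; the test of germ-cell RNA leaves its part open, because the testis fraction implied by spermatogenic miRNAs was 1.38 times that implied by piRNAs (32.9% and 23.8% of the testis level) against both testis libraries, 1.09 times against KO testis, and 1.88 times and past the bound of 1.5 against WT testis; without the doubted miR-871-3p it was 0.95, 0.84 and 1.08 times, all within the bound. That piRNAs are made by the caput itself cannot be told apart from this: 18.2% of WT caput piRNA reads were in sequences at least as frequent there as in testis, between the bounds of 10% and 50% set for that test. Sequences with no line in the testis files count among these, although those files leave out at least 52.6% (WT) and 54.3% (KO) of collapsed reads. Of the WT caput piRNA reads, 94.6% were in sequences listed in testis. A second form was added after the 18.2% was known. It gave an excess of 9.88 points over a testis sample of equal depth, just under its bound of 10. Together the forms leave caput-made piRNAs open. An effect of genotype is open too, since 1 pooled library per group cannot separate it from the dissection of that pool.

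The second pattern is the set of largest miRNA ratios at 13 months. Different names for 1 sequence are argued against, because 100% of the 23 cases (a miRNA in a tissue) with at least 1000 RPM that differ 4-fold by name still differed when reads were counted whatever their name, and 79 of 83 cases among all tested miRNAs did. Loss of reads with the usual first base in single libraries is a candidate explanation, since in 79.2% of 24 such cases (19), which cover 18 miRNAs, the reads starting 1 to 3 nt away did not follow, and in 54 of 77 cases among all tested miRNAs. Not following means under 2-fold or the other way, so these shares also hold cases that such a loss alone would not give. At other starts corpus miR-182-5p (-4.42) and miR-21a-5p (-3.46) and testis miR-99b-5p (3.61) and miR-871-3p (-1.96) went clearly the other way. Testis miR-743b-3p (0.88) went the same way, under 2-fold. What step would cause a loss of reads was not tested, and an effect of genotype on the first base stays open as untested. The caput differences of miR-871-3p and miR-34c-5p are among the 5 that did follow.

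The third pattern is the higher level of caput secretory genes in the KO caput transcriptome, with a median of 1.13 against 0.54 to 0.93 for random lists of like expression. Less muscle and connective tissue in the KO piece with no dilution of the WT library is argued against, since the medians of smooth muscle (0.40) and fibroblast markers (0.36) were above 0, with lowest members at 0.24 and 0.13. Less vessel is not decided, because the endothelial markers had a median of 0.13 with members from -0.37 to 0.49. Dilution of the WT library by testis RNA, alone or beside less of these tissues, cannot be told apart from an effect of genotype, because dilution would raise all genes that testis expresses little. Both tests set beforehand used the genes without testis fragments as reference and passed their bounds against these explanations: the secretory median lay 1.07 above the reference (bound 0.5), and the highest of the muscle, fibroblast and endothelial medians 0.35 above it (bound 0). These bounds were judged void after the results were seen, because the testis-fragment filter marked only 14 of the 1141 genes at least 8-fold lower (1.23%, against 1.9% of the tested genes), and even a limit of any read in both testis libraries marked 41.9% of them against 48.04% of the tested genes.

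Other differences between tissues were opposite in direction by shares of reads, and were not tested. Several of these oppositions depend on the counting: as distinct sequences tRNA was at -0.20 in corpus and -0.25 in cauda, and miRNA at -0.22, -0.19 and -0.01 in corpus, cauda and testis, while without the 10 most abundant sequences tRNA was at 0.62, 0.02 and 0.10. The KO minus WT log2 difference of the piRNA share was higher by 0.64 in corpus and by 0.66 in cauda than in testis. For the tRNA share it was -0.35 for caput minus corpus, 0.45 for corpus minus cauda and 0.22 for corpus minus testis. For the miRNA share it was 0.57 for caput minus corpus, -0.19 for corpus minus cauda and -0.10 for corpus minus testis.

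Missing ranks show that each small RNA file leaves out some collapsed reads, which were not analysed here. At least 24.4% of the collapsed reads had no line in WT caput at 13 months and 4.12% in KO caput. The values were 6.15% and 7.54% in corpus, 8.44% and 9.997% in cauda, 52.6% and 54.3% in testis, and 1.07% and 0.815% in caput at 2 months.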

How the results depend on the processing

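Of 780 values under an alternative for 202 results, 331 stayed the same, 415 moved and 34 reversed, and where no reason is given the cause was not tested. Among list medians 79 of 82 stayed the same and 0 reversed. Among class shares 18 of 141 and among named miRNAs 16 of 269 reversed. The alternatives differed between these kinds of result, so the counts do not rank list medians as steadier. Leaving out genes with testis fragments could not change a list without such a gene. Only the piRNA pathway and ER stress lists held any, with 1 tested gene each. Centring on the caput secretory list was applied to the counts of genes, not to the list medians. No paired analysis was possible because each group is 1 library, and leaving out a replicate was not possible either. Values below are log2, KO over WT unless stated, in the order caput, corpus, cauda, testis at 13 months and caput at 2 months. Depth limits the 2-month caput and the classes with few reads, and most class shares have narrow counting intervals, so that small shifts count as moved.

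Counting distinct sequences at equal depth gave piRNA values of -1.92 in caput, 0.42 in corpus, 0.14 in cauda and -0.05 in testis. It reversed tRNA in caput (1.43), corpus (-0.20) and testis (0.02), with 0.09 at 2 months, rRNA in caput (1.34) and at 2 months (0.03), and snoRNA in caput (1.58), corpus (-0.02) and cauda (-0.20). It also reversed snRNA in caput (1.29), corpus (-0.05) and at 2 months (-0.28), and miRNA in cauda (-0.19) and testis (-0.01). Sequences with 2 or more reads gave piRNA -4.69 in caput, 0.51 in corpus and -0.24 at 2 months, and tRNA -0.18 in caput and -0.24 in cauda. For these, testis over caput was 2.11 in WT and 6.77 in KO for piRNA and -3.89 in WT for tRNA, and cauda over caput was 0.82 in WT and 0.76 in KO for tRNA. Caput at 13 over 2 months was then -0.78 in WT and -0.33 in KO for miRNA and 4.49 and 4.31 for tRNA.

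Without the 10 most abundant sequences piRNA was at -4.87, 0.78, 0.79, -0.04 and -0.70, and tRNA at -0.32, 0.62, 0.02 (reversed), 0.10 (reversed) and -0.77. The miRNA share in testis (-0.05) and snRNA at 2 months (-0.23) reversed there. Reads of 24 to 32 nt gave piRNA -5.00, 0.66, 0.75, -0.02 and -0.63, and reads of 30 to 34 nt gave tRNA -0.10, 0.54, -0.01, 0.03 (reversed) and 0.02. Per miRNA read, piRNA was at -5.08, 0.68, 0.52 and -0.05. Without rRNA in the denominator, piRNA was at 0.62 in corpus and -0.02 in testis, and tRNA at 0.21 in corpus and -0.24 in cauda. That denominator gave 6.59 for piRNA testis over caput in KO, 0.76 and -3.72 for tRNA cauda and testis over caput in KO, and -0.81 and 4.44 for miRNA and tRNA at 13 over 2 months in WT.

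Of the alternatives chosen after seeing the data, reads without a mismatch gave piRNA -4.62 in caput, 0.62 in corpus, 0.57 in cauda and -0.27 at 2 months. Leaving out the dates gave piRNA -0.34 at 2 months and tRNA 4.47 in WT and 4.32 in KO at 13 over 2 months, and lengths of 18 to 38 nt gave miRNA -0.84 and -0.35.

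For miRNA counts, TMM gave 6 higher and 24 lower in caput and 1 higher at 2 months. Median of ratios gave 11 higher and 26 lower in caput, 12 higher in cauda and 1 higher at 2 months. Because more miRNAs are tested, 1 read or more gave 6 higher and 228 lower in caput, 122 and 35 in corpus, 77 and 15 in cauda, 24 and 43 in testis, and 39 and 3 at 2 months. Because fewer are tested, 1000 RPM or more gave 9 lower in caput, 10 higher in corpus, 9 higher and 2 lower in cauda, 4 and 7 in testis, and 3 higher at 2 months.

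Counting other first bases only, chosen after seeing the data, gave 8 higher and 11 lower in corpus, 9 and 1 in cauda, 3 higher in testis and 4 higher at 2 months. It reversed miR-27b-3p in caput (0.03), and in corpus miR-148a-3p (0.12), miR-145a-5p (0.25), miR-127-3p (-0.94), miR-21a-5p (-3.46) and miR-182-5p (-4.42). In cauda it reversed miR-16-5p (0.62), miR-21a-5p (0.28) and miR-27b-3p (-0.16), and in testis miR-34a-5p (0.06), miR-15b-5p (0.11), miR-99b-5p (3.61), miR-871-3p (-1.96) and miR-3107-5p/miR-486-5p (-0.15). Leaving out miRNAs with unequal first bases, also chosen then, gave 6 higher in corpus, 0 lower in cauda, and 4 higher and 9 lower in testis. All reads with the inner sequence, also chosen then, reversed miR-182-5p in corpus (-0.31) and miR-99b-5p in testis (1.62).

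In the transcriptome a pseudocount of 0.1 gave 698 higher genes and medians of -4.64 for the piRNA pathway, -3.56 for adipocyte markers and -0.81 for inflammatory cytokines, since it weighs low values more. A pseudocount of 5 gave 190 higher and 2073 lower genes. Centring on the caput secretory list, chosen after seeing the data, gave 8 higher and 8112 lower, which follows from its own median of 1.13.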

Other observations

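Beyond the comparisons above, single sequences of other small RNA classes were near equal or far apart between genotypes without a common direction. The most abundant snoRNA sequence of caput at 13 months, from SNORD52, was at 461 RPM of classified reads in WT and 441 in KO, and that of SNORD57 at 199.6 and 212. In testis a 31 nt U2 sequence was at 14.0 RPM in WT and 927 in KO. In cauda an 18 nt U2 sequence was at 10.7 RPM in WT and 137 in KO.

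Genes whose mRNA gave at least 10 RPM of small RNA fragments in both testis libraries numbered 285 of the 15000 tested genes (1.9%). Their median log2 difference in the caput transcriptome was -0.22 against 0.05 for the others, and 67 of them were lower and 0 higher in KO, a share of lower genes (23.5%) close to that of the others (22.1%).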
